A study of Nicotiana attenuata with 6 samples.

How the data were processed

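The series holds 6 single-colour arrays of floral buds of wild tobacco, Nicotiana attenuata, with 3 samples treated with a control solution and 3 with 1 µM coronatine. All plants carried the ir-aoc silencing construct against allene oxide cyclase. Per the labels, buds were taken 4 days after the corolla had emerged from the sepals, and a sample combined corolla, style and gynoecium tissue in equal shares. Each sample came from at least 20 flowers of 2 plants, where the labels leave open whether this number holds per plant. The replicates were independently made pools of cDNA. The labels' RNA extraction text names leaves while the tissue label names floral buds, and the samples were treated as floral buds. Groups and replicate numbers came from the sample titles.

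The scanner files hold spot intensity values made with Agilent Feature Extraction, version 9.1.1.1 per the file headers and 9.5 per the submitters' processing notes. Per the file headers, the processed signal of a spot was background-subtracted and spatially detrended, with surrogate values in place of signals too weak to measure, and it was not scaled between arrays. The mean signal and local background of each spot, also intensity values per the file headers, served only an alternative background correction. The flags for spots well above background, outlier spots and saturated spots were those of the scanner software, per the file headers. The series matrix holds deposited log2 values, which the authors normalized to the 75th percentile per the series' design text. Its columns had medians of -3.02, -3.08 and -3.02 for controls 1 to 3 and -3.09, -3.00 and -3.23 for coronatine 1 to 3, and 75th percentiles from 0.022 to 0.042. Each of 4 columns equalled log2 of its own array's processed signal minus a constant for 99.93% of probes, within 0.001 log2 units, so scale, centring and direction were known for them. The column of control 2 equalled the scanner file of coronatine 3 in the same way, and the column of coronatine 3 equalled none of the scanner files. The scanner files were therefore used for all results, and the matrix values as an alternative.

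Each array carried 45220 spots, of which 43803 were not control spots, for 43533 probes. Spots of 1 probe were averaged after outlier spots had been left out, which numbered 52 on control 1, 7 on coronatine 1 and 1 on each of the other arrays. No spot was saturated. Values were log2 of the processed signal minus the array's 75th percentile, so a value of 0 is the 75th percentile. A probe was tested when it lay well above background on all 3 arrays of at least 1 group, which left 27591 probes, and 25523 probes lay well above background on all 6 arrays. The 75th percentile of the processed signal was 177.1, 237.2 and 219.5 on controls 1 to 3 and 208.3, 271 and 278.2 on coronatine 1 to 3. The number of arrays limits the precision of every value.

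Coronatine and control were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with version 1.17.8 of data.table, and p-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. A second count took probes with a log2 change of at least 1. A probe that was not well above background on any array of a group has only a bound there. Its change is given as at least N-fold, the brighter group's mean against the mean, per array of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal. The p-values measure the spread between these samples, which were pools of cDNA. On simulated data for this comparison, made on 27534 probes, limma recovered 53% of 100 probes changed 2-fold and 83% of 100 changed 4-fold. Of 142 probes called there, 6 were unchanged, the shifted list was called, and 0 of 20 random lists were. The simulated noise was independent between probes, so the random lists cannot check list calls among correlated genes. Only these probes were changed, while the real comparison called 3470, so the recovered shares need not hold for the real data.

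A gene is the UniProt entry of the best hit of a probe's contig, as the annotation in the files gives it. The strength of each hit was not given in the sources used here, so an entry names a likeness and not a proven orthologue. Of all probes, 33639 carried an entry, 14125 of them 1 of 5651 plant entries and 19514 an entry of another kingdom, and 9894 carried none. The table of gene names supplied as reference held no identifier of these contigs and was not used. Genes were taken from plant entries only, and where several probes shared an entry, the probe with the highest mean signal stood for the gene. Coordinates were not analysed here.

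The groups, the tests, the alternatives, 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took the allene oxide cyclase probes, the 8 largest rises and the 8 largest falls past the threshold without overlap between the groups, among the probes that stood for a gene with an informative name and with 1 gene per product name, up to 3 members past the threshold with the largest change in each list, and, whatever their p, entries for COI1, JAR4 or JAR6, MYB305, EOBII, ODORANT1, chalcone synthase, phenylalanine ammonia-lyase, nectarins and SWEET9. The files gave short entry names and not product names, so each list was translated from the fixed product names to entry names after the names had been seen and before any value was computed. Some genes named in the results were not picked by this rule. They are TI11A_ARATH, TIF3B_ARATH, CAMT1_TOBAC, COMT1_COFCA, AROD2_ARATH, C75A3_PETHY, ETR1_TOBAC, H2A1_SOLLC, SEP3_ARATH, AG_PANGI, AP3_ARATH and SPS_BETVU, besides those of the pollen, laccase and secondary wall lists.

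The 31 lists were jasmonate biosynthesis, jasmonate signalling and turnover, jasmonate-inducible anti-herbivore proteins, nectary and nectar, sucrose and starch metabolism, shikimate, phenylpropanoid and benzenoid volatile synthesis, flavonoid and anthocyanin synthesis, polyamines and phenolamides, nicotine synthesis, terpenoid synthesis, cell wall loosening, aquaporins, ethylene synthesis and perception, ethylene response factors, MYB, WRKY and NAC factors, auxin response, gibberellin synthesis and response, pathogenesis-related and antimicrobial proteins, senescence and proteolysis, photosynthesis, pollen and anther, style, stigma and transmitting tissue, ovule and seed, floral organ identity, cytosolic ribosomal proteins, histones and cell cycle, heat shock proteins, circadian clock, and cuticle and very-long-chain lipids. Each of the 28 lists with at least 5 genes was compared with all other probes by limma's camera with a preset correlation of 0.01, adjusted over these lists.

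Alternatives changed the background correction (normexp with an offset of 50), the scaling (quantile, median, or the 75th percentile over probes detected on all arrays), the filter on dim probes, a floor, the variance model, array weights, the replicate number as a block, the slide, and the values (series matrix). They also included significance analysis of microarrays with all 20 label permutations at a false discovery rate of 5%, which the series' design text names, treat against a log2 change of 0.5, camera with an estimated correlation, fry, all probes of a list, and leaving out each array. The arrays lay on 5 slides, with control 1 and coronatine 3 on 1 slide. Figures were drawn with matplotlib 3.10.9.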

Results

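Transcripts of floral buds of wild tobacco, Nicotiana attenuata, were measured on 6 arrays, with 3 arrays of buds that had received a control solution and 3 of buds that had received 1 µM coronatine. Coronatine is a bacterial toxin that mimics jasmonoyl-isoleucine, the active jasmonate hormone. All plants were silenced for allene oxide cyclase, an enzyme of jasmonate synthesis, so both groups carried the construct. Jasmonate itself was not measured on these arrays. Buds were taken 4 days after the corolla emerged, and each sample combined corolla, style and gynoecium. The 75th percentile of the signal lay between 177.1 (control 1) and 278.2 (coronatine 3), and 61.64% (control 1) to 67.52% (coronatine 2) of the probes lay well above background. Genes are named by the UniProt entry of the best plant hit of a contig, followed where needed by the contig.

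Some transcripts typical of mature pollen were far higher on control 1 than on the other arrays, while 11 of the 23 probes listed for such transcripts were well above background on all 6 arrays. Of the 23 probes, 12 lay more than 2 log2 units higher on control 1 than on the mean of controls 2 and 3, and the median of the 23 differences was 2.07. Of the 12, 11 were not well above background on controls 2 and 3. With each array at its lowest detected signal, 10 probes were more than 2 higher and the median was 1.02. This list was written after the arrays had been compared and left out the entries noticed there. It kept only probes well above background on at least 1 array. A probe detected on control 1 alone, such as that of ADF10_ARATH, thus entered only through its high value there. A probe of the petunia pollen pectinesterase PME_PETIN (Na_454_04623) stood at 2.72 on control 1, at -0.33 on coronatine 2 and at -5.06 or lower on the remaining 4 arrays. A probe of the sugar transporter STP4_ARATH stood at 2.56 on control 1, at -0.52 on coronatine 2 and at -5.77 or lower elsewhere. Without control 1 and coronatine 2, a setting chosen after the data had been seen, 1850 probes changed.

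**Figure D1:**
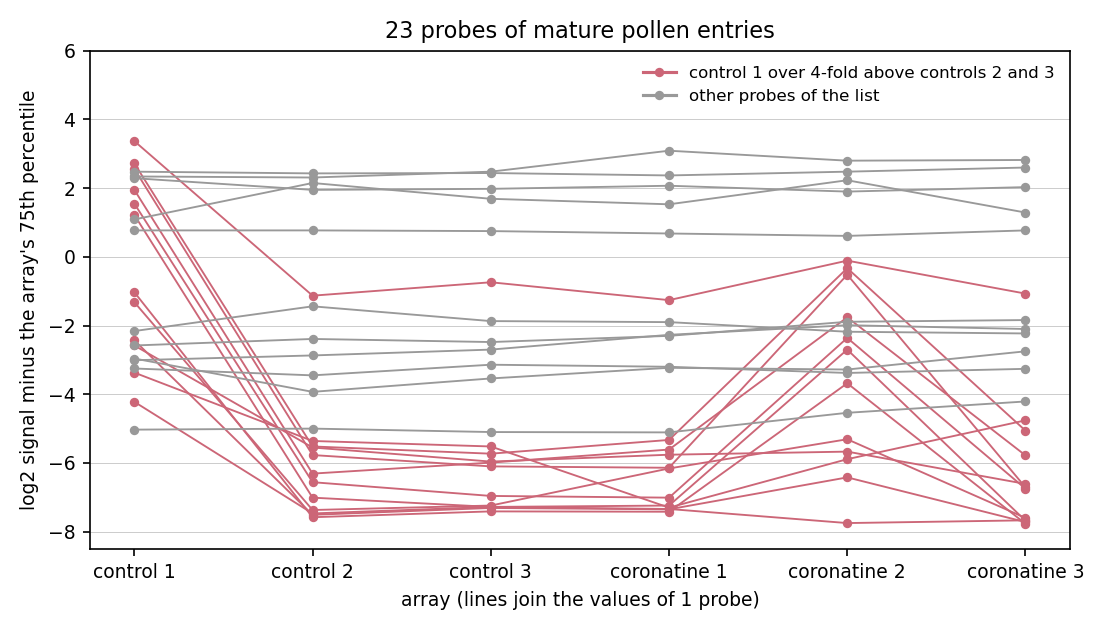
Log2 signal minus the array's 75th percentile (y axis) of 23 probes of mature pollen entries on the 6 arrays (x axis), with a line for each probe. The 12 probes drawn in red lay more than 2 log2 units higher on control 1 than on the mean of controls 2 and 3, where 11 of them were not well above background, and several of them were also raised on coronatine 2.

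Allene oxide cyclase, the silenced gene, was looked up by 3 probes of the entry AOC2_ARATH, and limma called 0 of the 2 probes tested. Which of these contigs belongs to the silenced gene is not known. Na_454_42716 had mean values of 0.11 ± 0.09 in control and 0.56 ± 0.18 in coronatine buds (SD, n = 3), a log2 difference of 0.45 (SE 0.12, adjusted p of 0.0585). Na_454_02007 pointed the other way, with a difference of -0.51 (SE 0.21, adjusted p of 0.166). The third probe, Na_454_28839, lay well above background on 0 control and 2 coronatine arrays and was not tested. Because both groups carried the construct, these values do not check the group labels. The adjusted p of Na_454_42716 passed the threshold with normexp background correction (0.0312), with the 75th percentile over detected probes (0.0488), with an intensity trend (0.0313) and with array weights (0.0301), and significance analysis of microarrays called it too.

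The comparison asked which transcripts of buds that carry the construct respond when coronatine is supplied. Coronatine buds had higher transcripts for some jasmonate repressors of the TIFY family, some proteinase inhibitors, some chalcone synthases and some anthocyanin enzymes, for linalool synthase and for some enzymes of ethylene synthesis. Other enzymes of the flavonoid and anthocyanin list were lower, with 7 genes higher and 6 lower in all. Transcripts for phenylalanine ammonia-lyase and cinnamate hydroxylase, and for several sucrose synthases, laccases, histones, cyclins, ribosomal proteins and MADS box genes, were also lower. Of 27591 probes, 3470 changed, 1618 higher and 1852 lower, and 989 changed at least 2-fold, 500 higher and 489 lower. At an unadjusted p under 0.05 there were 8564. In 10755 probes (39.1%) the groups did not overlap, against 10% by chance for 3 against 3 arrays. Of the 3470, 1440 carried a plant entry, 572 were unnamed and 1458 had a best hit outside plants. The median change of all probes tested was -0.01.

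The cytochrome P450 C79A2_ARATH, which turns phenylalanine into its aldoxime, rose by 4.76 (SE 0.64, adjusted p of 0.0135). It was well above background on only 1 control array, with a change of 3.74 with each array at its lowest detected signal, and the other probe of this entry tested gave -1.03. The fatty acyl-CoA reductase FACR1_ARATH, of an enzyme family that makes fatty alcohols for surface lipids, rose by 4.67 (SE 0.32, adjusted p of 0.00418) and was well above background on all 6 arrays, and 2 of its 4 probes rose. The endochitinase CHI4_PHAVU rose by 3.41 (SE 0.32), while its other probe gave -0.16. The P450 C04C1_PINTA rose by 3.06 (SE 0.37) and the ethylene-responsive factor ERF17_ARATH by 3.02 (SE 0.53), both well above background on 1 control array only, with changes of 2.56 and 2.15 with each array at its lowest detected signal. Larger changes on probes that did not stand for a gene were not ranked. For 3 of the top rises no control array was well above background: the flavanone hydroxylase FL3H_PETCR was at least 3.58-fold higher, the carbonic anhydrase CAHC_TOBAC at least 5.68-fold and the chalcone synthase CHS2_SOLLC at least 3.23-fold. Among the largest falls, no coronatine array was well above background for FLA14_ARATH (at least 3.84-fold lower), GST11_ARATH (at least 4.03-fold), EXTN3_ARATH (at least 3.16-fold) and LAC10_ARATH (at least 2.19-fold). They encode an arabinogalactan protein, a glutathione transferase, an extensin of the cell wall and a laccase. These bounds hold for the main background subtraction only. With normexp CAHC_TOBAC, CHS2_SOLLC and LAC10_ARATH gave 0.506, 0.251 and -0.428 and were not called. Over the alternatives on the scanner files FL3H_PETCR ran from 0.429 to 4.221 and FLA14_ARATH from -4.456 to -0.678. The expansin-like EXLB1_ARATH fell by 2.53 (SE 0.63), the laccase LAC2_ARATH by 2.45 (SE 0.46), the cinnamate hydroxylase TCMO_ZINEL by 2.36 (SE 0.43) and the sesquiterpene synthase HUMS_ARATH by 2.27 (SE 0.32). The other probes of EXLB1_ARATH and LAC2_ARATH gave -0.04 and -0.31 and were not called.

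The jasmonate signalling and turnover list shifted up, with a median log2 change of 0.42 over 20 genes and an adjusted p of 0.00131. With an estimated correlation camera gave an adjusted p = 0.2002. The estimate was -0.0084, below the preset 0.01, so the size of the correlation does not account for the lost call. Of the list's 20 genes 7 rose and 0 fell, and 10 rose and 0 fell adjusted over the list alone. They included TI11B_ARATH at 1.07 (SE 0.25), TI11A_ARATH at 1.01 (SE 0.13) and TIF3B_ARATH at 0.81 (SE 0.12), members of the TIFY family of repressors whose transcripts are known to be induced by jasmonates. TIF5A_ARATH was at least 2.08-fold higher. The hydrolase ILL1_ARATH, of a family that splits hormone conjugates with amino acids, was at least 2.69-fold higher. With normexp background correction TI11B_ARATH, TIF5A_ARATH and ILL1_ARATH were not called, with values of 0.048, 0.02 and 0.103, and the median of the list was 0.084. Over all 36 probes of the list, 10 rose and 3 fell. The 7 jasmonate biosynthesis genes had a median of 0.24 (adjusted p of 0.0605), with 0 past the threshold by limma, over all probes or adjusted over the list alone, against 2 at an unadjusted p under 0.05 and 1 by significance analysis of microarrays. That list passed without control 1 (adjusted p of 0.0101) and without coronatine 3 (0.0474). Among the anti-herbivore proteins, 4 of 15 rose and 0 fell, and 4 rose and 2 fell adjusted over the list alone. The proteinase inhibitors ICID_SOLTU, IP2X_SOLTU and ICI1_SOLLC, which block the digestive proteases of insects, rose by 1.35 (SE 0.13), 1.09 (SE 0.22) and 1.08 (SE 0.19). Other members pointed down and were not called over all probes. ITR1_NICSY had a difference of -1.18 (SE 0.41, adjusted p of 0.112) and THD1_SOLTU of -0.74 (SE 0.20, adjusted p of 0.0613). The anti-herbivore list as a whole was not called (adjusted p of 0.758), and its median of -0.06 lay opposite to its mean of 0.09 and its test.

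**Figure D2:**
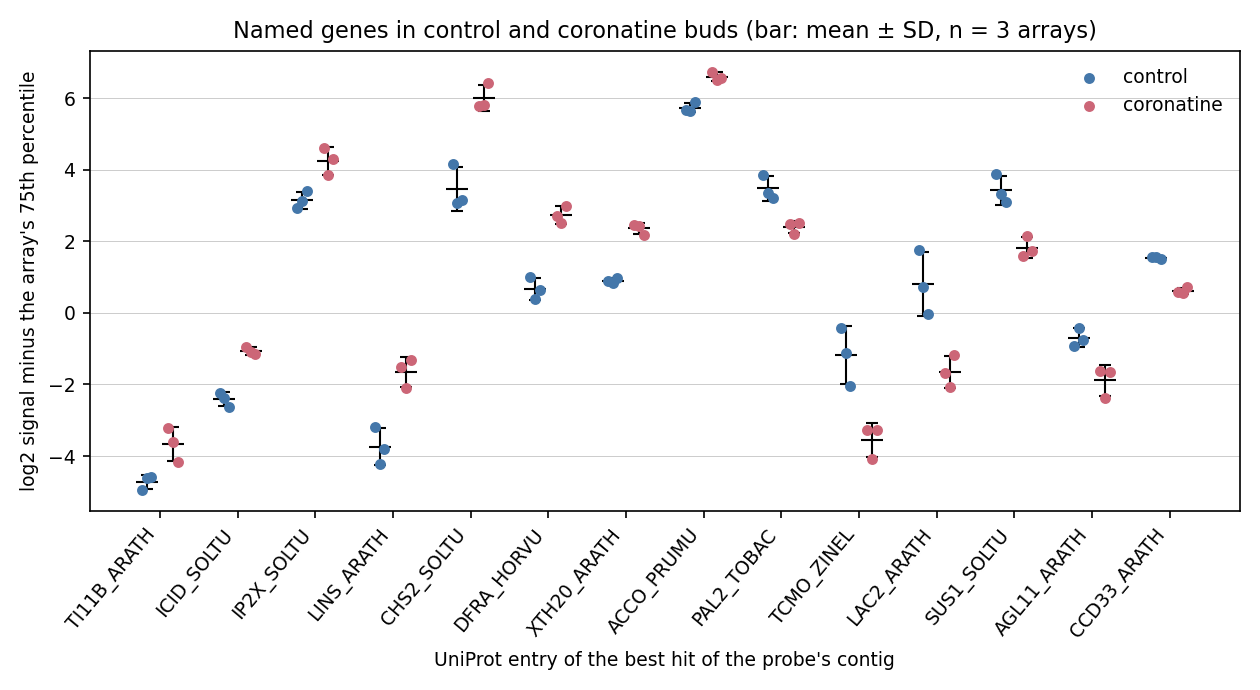
Log2 signal minus the array's 75th percentile (y axis) of 14 named genes (x axis) on 3 control arrays (blue) and 3 coronatine arrays (red), with mean ± SD as black bars. In every gene shown the 3 arrays of 1 group lie above the 3 of the other, as for CHS2_SOLTU with means of 3.45 in control and 6.003 in coronatine.

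Most phenylpropanoid genes that changed were lower, while chalcone synthase was higher. The shikimate, phenylpropanoid and benzenoid list had the lowest median among the lists called, -0.47 over 38 genes (adjusted p of 0.00131, and adjusted p = 0.734 with an estimated correlation), with 3 genes higher and 16 lower, and 4 and 20 adjusted over the list alone. Each of the 5 phenylalanine ammonia-lyase entries tested fell, among them PAL2_TOBAC by 1.08 (SE 0.19) and PAL3_TOBAC by 1.37 (SE 0.24). This enzyme opens the pathway to lignin, flavonoids and benzenoid scent. The methyltransferases CAMT1_TOBAC and COMT1_COFCA of lignin synthesis fell by 1.65 (SE 0.27) and 1.56 (SE 0.28), and arogenate dehydratase AROD2_ARATH, a step of phenylalanine synthesis, by 0.62 (SE 0.11). The chalcone synthase CHS2_SOLTU, the first enzyme of flavonoid synthesis, rose by 2.55 (SE 0.33), from 3.45 ± 0.61 to 6.003 ± 0.37 (SD, n = 3). Another chalcone synthase entry, CHSA_PETHY, had a difference of -0.36 (SE 0.19, adjusted p of 0.244), and CHSD_PETHY was not well above background on any array. In the flavonoid and anthocyanin list 7 genes rose and 6 fell of 36, with 9 and 9 adjusted over the list alone, and the list was not called (median 0.09, adjusted p of 0.299). Dihydroflavonol reductase DFRA_HORVU rose by 2.06 (SE 0.20) and the glucosyltransferase UFOG_SOLME by 2.00 (SE 0.24), while the flavonoid hydroxylase C75A3_PETHY fell by 1.02 (SE 0.13).

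ODORANT1 (ODO1_PETHY), a petunia regulator of benzenoid scent, had a difference of 1.16 (SE 0.37, adjusted p of 0.0905) and was well above background on 1 control array. It passed without control 1 (adjusted p of 0.0105), with array weights (0.0133), without control 1 and coronatine 2 (0.0250) and by significance analysis of microarrays, while normexp gave -0.003. MYB305 (MYB05_ANTMA), a regulator of nectary genes, had a difference of -0.59 (SE 0.37, adjusted p of 0.328) and was the only gene of the nectary list measured, where adjusting over the list alone is the same as no adjustment and called 0. The nectarin entries NEC1_NICLS and NEC3_NICLS were not well above background on any array. No probe carried an entry named for COI1, JAR4, JAR6, EOBII or SWEET9. This is an absence of names only, and such genes may have been measured under other entries.

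Terpenoid genes shifted up, with a median of 0.40 over 12 genes (adjusted p of 0.0385, and adjusted p = 0.368 with an estimated correlation), 3 of them higher and 0 lower, and 4 and 0 adjusted over the list alone. Linalool synthase LINS_ARATH, which makes a floral volatile, rose by 2.09 (SE 0.31). Cineole synthase CINS_ARATH rose by 0.88 (SE 0.22), with 1 of its 2 probes tested past the threshold. HMDH3_SOLTU, the rate-limiting enzyme of the mevalonate pathway, rose by 0.86 (SE 0.13). The humulene synthase HUMS_ARATH, which fell, was not among the entries this list had fixed. The call was lost without control 2 (adjusted p of 0.0744), with all probes of the list (0.0569) and with a floor (0.0564). Aquaporins, the water channels of growing cells, had a median of 0.28 over 24 genes (adjusted p of 0.0461, and adjusted p = 0.769 with an estimated correlation), with 3 higher and 0 lower, and 3 and 0 adjusted over the list alone. TIP2_TOBAC rose by 1.03 (SE 0.17), while 1 of the 3 probes of TIP11_ORYSJ rose and 1 fell. The aquaporin call was lost without control 2 (0.163), control 3 (0.107), coronatine 1 (0.144) or coronatine 2 (0.0969), and the median was -0.01 between the 2 arrays that shared a slide. Of 84 cell wall loosening genes 16 rose and 9 fell, with 27 and 14 adjusted over the list alone, and the list was not called (median 0.19, adjusted p of 0.0569). It passed without control 3 (0.0310) and without coronatine 3 (0.0253). The xyloglucan transferase XTH20_ARATH rose by 1.46 (SE 0.11), and the pectinesterase PME38_ARATH fell by 1.91 (SE 0.44).

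Several genes of ethylene synthesis rose. ACC synthase 1A11_PRUMU and the ACC oxidases ACCO3_CUCME and ACCO_PRUMU, the last enzymes of ethylene synthesis, rose by 0.85 (SE 0.10), 0.96 (SE 0.12) and 0.87 (SE 0.11). A second, dimmer probe of ACCO_PRUMU fell by 0.93. The receptor ETR1_TOBAC fell by 0.82 (SE 0.14). Of the 25 genes of ethylene synthesis and perception 4 rose and 1 fell, with 5 and 4 adjusted over the list alone, and the list was not called (adjusted p of 0.570), its median of -0.01 being opposite in sign to its mean of 0.07 and its test. Of 48 ethylene response factors 2 rose and 3 fell, with 2 and 1 adjusted over the list alone, and ERF16_ARATH rose by 2.37 (SE 0.29). That list was not called either (adjusted p of 0.882), with a median of -0.06, a mean of 0.06 and a test pointing down.

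The lists of ribosomal proteins, of histones and cell cycle and of floral organ identity shifted down. The 88 cytosolic ribosomal protein genes had a median of -0.27 (adjusted p of 4.76e-10, and adjusted p = 0.597 with an estimated correlation), and their quartiles ran from -0.31 to -0.16. Of these 0 rose and 7 fell, such as RL132_BRANA by 0.48 (SE 0.09), while 0 passed limma adjusted over the list alone, against 50 at an unadjusted p under 0.05 and 46 by significance analysis of microarrays. The histone and cell cycle list had a median of -0.24 over 59 genes (adjusted p of 0.00131, and adjusted p = 0.223 with an estimated correlation), with 0 genes higher and 18 lower, and 2 and 26 adjusted over the list alone. The D-type cyclins CCD61_ARATH, CCD33_ARATH and CCD21_ARATH, which drive entry into the cell cycle, fell by 0.96 (SE 0.19), 0.93 (SE 0.09) and 0.92 (SE 0.15). Histone H2A1_SOLLC fell by 0.82 (SE 0.09). The floral organ identity list was matched on names such as MADS box and agamous, so it was not limited to organ identity genes. It had a median of -0.30 over 32 genes (adjusted p of 0.00131, and adjusted p = 0.2002 with an estimated correlation). Of these 2 were higher and 10 lower, and 2 and 12 adjusted over the list alone. MADS3_ORYSJ, of the AGAMOUS class, and AGL11_ARATH, which specifies ovules, fell by 1.19 (SE 0.16) and 1.19 (SE 0.25), and SEP3_ARATH, needed for petals, stamens and carpels, fell by 0.93 (SE 0.14). AG_PANGI, also of the AGAMOUS class that specifies stamens and carpels, rose by 0.86 (SE 0.13), and AP3_ARATH, of the petal and stamen class, by 0.79 (SE 0.17). Looked up by class after the results were seen, 6 carpel and ovule identity genes had a median of 0.19. The 4 petal and stamen identity genes had a median of -0.01. The fall of the list thus did not extend to these identity classes as a set.

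Among other transcription factors, NAC factors had a median of -0.27 over 21 genes (adjusted p of 0.0385, and adjusted p = 0.734 with an estimated correlation), with 1 higher and 2 lower, and 2 and 5 adjusted over the list alone. NAC69_ARATH fell by 0.81 (SE 0.14), NAC7_ARATH was at least 2.21-fold lower, and NAC29_ARATH, a regulator of leaf senescence, rose by 1.42 (SE 0.27) on 1 probe while another probe of it fell. The NAC call was lost without control 1 (0.149), with normexp (0.141), without a filter (0.0909), with probes detected on all arrays (0.134), with array weights (0.0822) and with the slide as a block (0.0562). Of 21 MYB factors 1 rose and 4 fell, with 3 and 5 adjusted over the list alone (median -0.04, adjusted p of 0.882). MYB86_ARATH fell by 1.34 (SE 0.19), with 1 of its 3 probes tested past the threshold. Of 25 WRKY factors 0 rose and 3 fell, also adjusted over the list alone (median -0.12, adjusted p of 0.194), and WRK26_ARATH fell by 0.94 (SE 0.12).

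**Figure D3:**
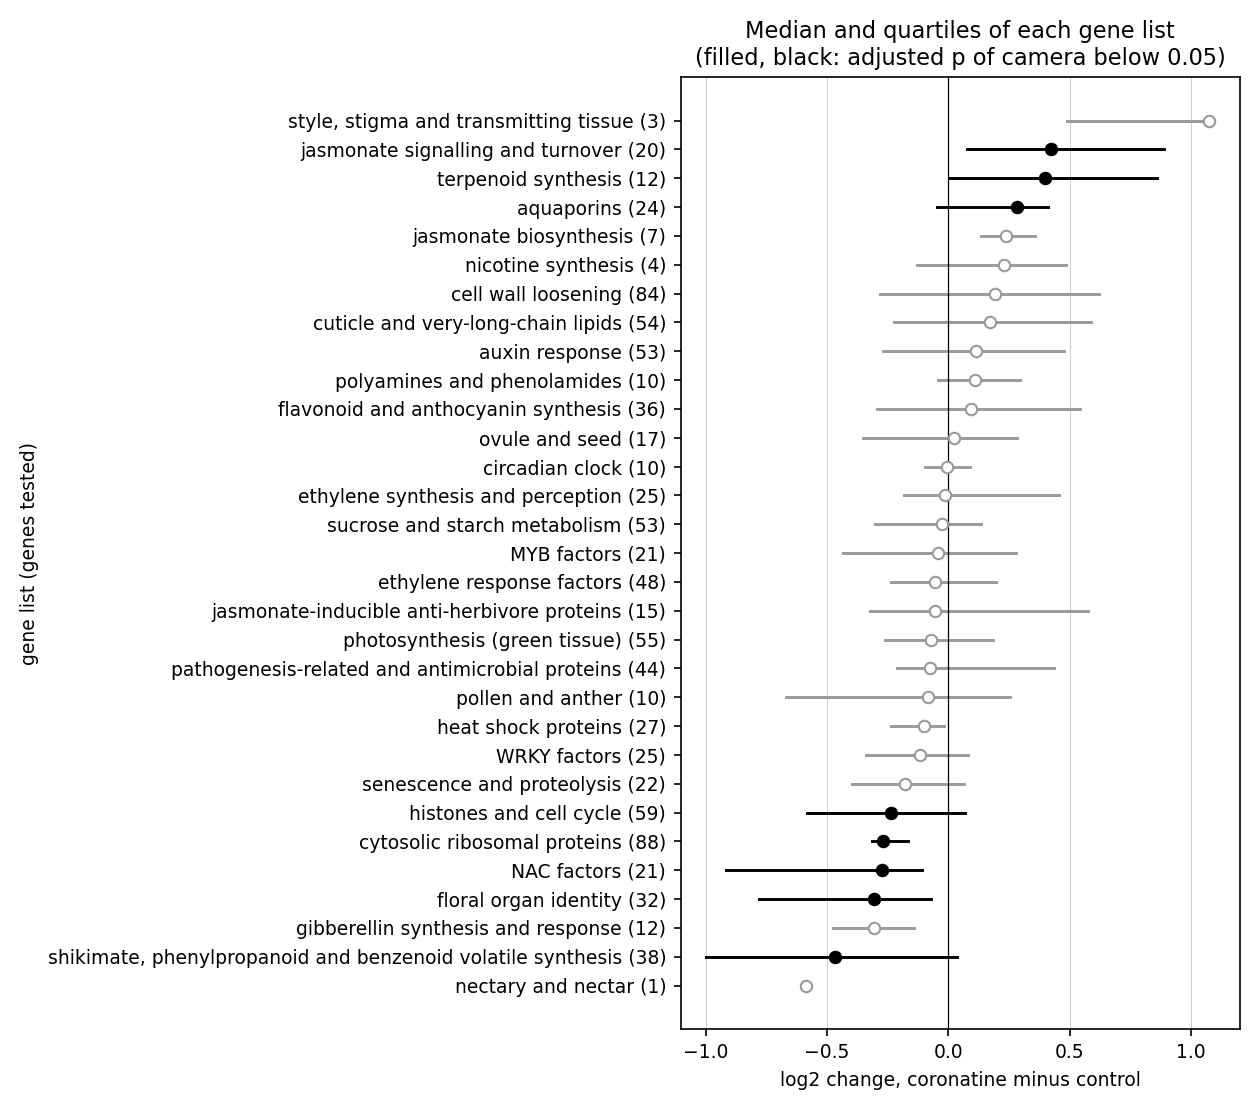
Median log2 change from control to coronatine (points, x axis) with the first and the third quartile (lines) of 31 gene lists (y axis, number of genes tested in brackets). Lists in black were past an adjusted p of 0.05 in camera, 3 of them above 0 and 5 below, and 0 lists passed with an estimated correlation.

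Auxin response genes went both ways, 8 higher and 6 lower of 53, with 17 and 9 adjusted over the list alone (median 0.11, 0.08 with genes below background at their bound, adjusted p of 0.220). Genes at their bound moved the median of no other list. IAA5_ARATH rose by 1.16 (SE 0.17), and the auxin exporter PIN4_ARATH fell by 1.00 (SE 0.15). Of 12 gibberellin genes 0 rose and 2 fell, with 0 and 3 adjusted over the list alone (median -0.31, adjusted p of 0.0605, and 0.0495 without coronatine 2), namely the gibberellin oxidases GAO1B_WHEAT by 1.20 (SE 0.30) and GAOX1_ORYSJ by 0.97 (SE 0.17). In sugar metabolism, the sucrose synthases SUS1_ARATH and SUS1_SOLTU fell by 1.69 (SE 0.33) and 1.60 (SE 0.24), with 2 of the 4 SUS1_SOLTU probes tested lower. The beta-amylase AMYB_HORVU fell by 1.43 (SE 0.23). Sucrose-phosphate synthase SPS_BETVU, chosen after its value was seen and well above background on 1 control array, rose by 1.20 (SE 0.11). Of the 53 genes 3 rose and 4 fell, with 5 and 4 adjusted over the list alone (median -0.03, adjusted p of 0.882). Of 44 pathogenesis-related genes 6 rose and 0 fell, also adjusted over the list alone, while of all 101 probes of the list 9 rose and 7 fell (median -0.16). The list was not called (median -0.08, mean 0.11, test up, adjusted p of 0.570). The glucanase E13I_TOBAC rose by 1.51 (SE 0.24) and PR5_ARATH by 0.76 (SE 0.18), with 2 of 6 PR5_ARATH probes higher.

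Cuticle and very-long-chain lipid genes were 5 higher and 5 lower of 54, with 11 and 7 adjusted over the list alone (median 0.17, adjusted p of 0.165), and the list passed without control 1 (0.0261). Besides FACR1_ARATH, the lipases GDL9_ARATH and GDL40_ARATH fell by 1.84 (SE 0.35) and 1.80 (SE 0.33), though another probe of GDL9_ARATH rose. Heat shock proteins were 1 higher and 1 lower of 27, with 1 and 0 adjusted over the list alone and 6 and 1 of all 43 probes (median -0.10, adjusted p of 0.381), and the plastid chaperone HSP21_PEA rose by 1.91 (SE 0.26). Clock genes were 2 higher and 2 lower of 10, also adjusted over the list alone (median -0.01, mean 0.13, test up, adjusted p of 0.882), and PRR1_ORYSJ rose by 1.34 (SE 0.21) while ADO1_ARATH, a clock photoreceptor, fell by 0.68 (SE 0.09). Of 10 polyamine and phenolamide genes limma called 0, also adjusted over the list alone (median 0.11, adjusted p of 0.222), against 4 at an unadjusted p under 0.05 and 3 by significance analysis of microarrays. Among 22 senescence and proteolysis genes limma called 0, while of all 58 probes of the list 2 were higher and 3 lower, and 9 genes had an unadjusted p under 0.05. Adjusted over the list alone, 2 were higher and 4 lower (median -0.18, adjusted p of 0.299). The 4 nicotine genes were too few for a list test and 0 passed limma, with 1 higher and 1 lower adjusted over the list alone and 2 at an unadjusted p under 0.05 (median 0.23). Over all 8 nicotine probes the median was -0.59, with 0 higher and 3 lower.

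Markers of tissues the buds could hold gave no called list. Of 55 photosynthesis genes 1 rose and 4 fell, also adjusted over the list alone (median -0.07, adjusted p of 0.639). Those that fell were plastid-encoded, such as RBL_NICTO by 0.58 (SE 0.12), and the chlorophyll-binding CB21_LEMGI rose by 0.70 (SE 0.13). Of 10 pollen and anther genes 0 rose and 1 fell, with 1 and 1 adjusted over the list alone and 5 higher and 2 lower of all 27 probes (median -0.09, mean -0.19, test up, adjusted p of 0.882). The tapetal TAP1_ANTMA fell by 1.24 (SE 0.14), with 1 of its 3 probes tested lower. Of 17 ovule and seed genes 0 rose and 2 fell, also adjusted over the list alone (median 0.02, mean -0.06, test down, adjusted p of 0.964), and the embryogenesis protein LEAD7_GOSHI fell by 1.70 (SE 0.25). Of 3 style genes, too few for a list test, 2 rose and 0 fell, also adjusted over the list alone (median 1.08), while over all 9 style probes the median was 0.01, with 4 higher and 1 lower. The 2 genes that rose were the pistil ribonucleases RNS6_NICAL and RNS7_NICAL, at 1.12 (SE 0.24) and 1.08 (SE 0.24).

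Counts over all probes of a list, and not only the brightest of each entry, differed for other lists too. They were 3 higher and 2 lower of 47 aquaporin probes, 4 and 1 of 18 terpenoid probes, 3 and 4 of 40 NAC probes, 1 and 3 of 29 gibberellin probes, 5 and 4 of 45 probes for ethylene synthesis and perception, 0 and 1 of 17 polyamine probes, 11 and 12 of 122 cuticle probes, 5 and 5 of 26 clock probes and 3 and 51 of the probes for histones and cell cycle. For flavonoids they were 14 and 12 of 88, with a median of -0.02 where the genes gave 0.09.

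The changes were larger than the spread between replicates in limma, and 8 of the 28 lists tested were called, 3 up and 5 down, against 0 by camera with an estimated correlation (3 at an unadjusted p under 0.05). Fry, which tests a list's own genes for a shift and does not compare them with other probes, called 5 of these 8 and 3 other lists. The number of changed probes depended on single arrays. It was 3830 without control 1, 707 without control 2, 1864 without control 3, 43 without coronatine 1, 965 without coronatine 2 and 282 without coronatine 3, and at least 2-fold changes numbered 434 without control 2, 43 without coronatine 1, 608 without coronatine 2 and 230 without coronatine 3. Of the 86 named genes past the threshold, 71, 35 and 67 stayed past it without control 1, 2 and 3, and 4, 40 and 13 without coronatine 1, 2 and 3. The groups did not overlap in any of these genes, so leaving out 1 array could not turn their direction. The count was 739 without a filter on dim probes, 5285 with array weights and 7670 with significance analysis of microarrays. It was 0 in the series matrix, where 204 probes had an unadjusted p under 0.05, and 30 of the 86 genes had the opposite sign there. That matrix holds the scanner values of coronatine 3 as control 2. Leaving control 2 and coronatine 3 out of the scanner files, a setting chosen after the results were seen, also gave 0. There 5367 probes had an unadjusted p under 0.05. With normexp 72 of the 86 stayed past the threshold, and the 14 lost included CAHC_TOBAC, CHS2_SOLLC, ERF17_ARATH, LAC10_ARATH, ICI1_SOLLC, NAC7_ARATH and PALY_HELAN.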

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

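Chosen only after the results were seen were the tests of exchanged scanner files, of a control sample in the file of coronatine 3, of the shared slide, of anther or pollen tissue, of the share of ovary, and the counts over other splits of the arrays. The tests of another tissue in the matrix column, of noise on dim probes, of mature pollen and of brightness had their bounds written before their values were computed, although the mature pollen list was drawn up after a first look at control 1 and left out the entries seen there.

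The series matrix column of coronatine 3 held signal that the comparisons did not use, with 2185 of 27591 probes at least 4-fold above all 4 columns that match their scanner files and 4672 at least 4-fold below. The column of control 2 equals the scanner file of coronatine 3. An exchange of the scanner files of control 2 and coronatine 3 is argued against, since 0.06% of probes were equal between the matrix column of coronatine 3 and the scanner file of control 2, and so is a control sample in the scanner file of coronatine 3, whose lowest correlation with coronatine 1 and 2 over detected probes (0.9923) lay 0.0109 above its highest with controls 2 and 3 (0.9814), and 0.9879 against 0.9853 over all probes. Another tissue in the matrix column stays open. Of the 4 lists named for it, style lay at -10.54, photosynthesis at -7.41, pollen and anther at -4.38 and ovule and seed at 0.66 relative to the matching columns. Floral identity, not named beforehand, lay at -4.04 and ribosomal proteins at 1.23. What that tissue may be was not tested. The design sets no tissue apart from another, so no biological explanation was tested.

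Control 1 stood apart, with 329 probes at least 4-fold above each of the other 5 arrays, against 22 to 74 for the others, and for 217 of the 329 (66%) coronatine 2 was next highest. A shared slide is argued against by the correlation of -0.03 between its deviations and those of coronatine 3, and noise of dim probes by a spread 1.68 times that between controls 2 and 3 among the 9178 brightest probes. Mature pollen carried over may explain part of it. The median of 23 mature pollen probes was 2.07 higher than in controls 2 and 3. It was only 1.02, just past the bound of 1, with each array at its lowest detected signal. This median cannot decide the question, because the list kept only probes well above background on at least 1 array. Probes detected on control 1 alone, such as those of ADF10_ARATH and PEL59_SOLLC, entered only through their high value there. The profilin PROF3_TOBAC, well above background on all 6 arrays, was 4.30 higher. A probe of the pectinesterase PME_PETIN (Na_454_04623) was at least 7.96 higher. Of the 23 probes, 11 were well above background on all 6 arrays. The pollen and anther list, at 0.32, met the bound set against anther tissue, which was still left undecided, because 2 of its 10 genes rose steeply, POLC3_OLEEU to 1.33 from -4.17 and -3.39 on controls 2 and 3 and POLC1_TOBAC to 0.59 from -5.11 and -4.42, while most of the others were bright on all 6 arrays, which would hide a small share. The design gives no difference between replicates, so no biological explanation was tested.

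Ribosomal protein and histone lists were lower with coronatine, by medians of -0.27 and -0.24. A scaling error that depends on brightness is argued against, since 0% of 10000 random lists matched on signal had a median as low as the ribosomal list (lowest -0.19) and 0.01% as low as the histone list (lowest -0.25). For the histone list, a smaller share of ovary among the pooled organs could not be decided, with carpel and ovule identity genes (median 0.19, 6 genes) 0.21 above petal and stamen identity genes (median -0.01, 4 genes), which met the bound set against it but lay within the standard error of 0.44. Most of these 6 genes were of the AGAMOUS class, which specifies stamens as well as carpels. Of the 6, AGL11_ARATH, which specifies ovules, and MADS3_ORYSJ each fell by 1.19, AG_PANGI rose by 0.86, and the others were not called. A response to coronatine, the treatment that the design names, stays open beside a smaller share of ovary. With estimated correlations neither the ribosomal nor the histone list was called by camera (adjusted p of 0.597 and 0.223).

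The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed probes 1 of the 10 splits, the real one, gave 3470, with 0 by limma as the highest of the others, where 399 to 1375 probes had an unadjusted p under 0.05. For changes of at least 2-fold 1 of the 10 splits, the real one, gave 989, with 0 as the highest of the others. All other splits put arrays of both groups on each side. A difference between the groups, whatever its cause, then adds to the spread within the sides and lowers the count. The 0 of the other splits was therefore largely set in advance. For called lists 3 of the 10 splits gave 8 or more, with 8 for the real split and 9 as the highest of the others. The split with 9 joined control 1 with coronatine 2 and coronatine 3, and 1 other split, which joined control 1 with coronatine 1 and coronatine 2, gave 8. Both hold the 2 arrays with raised pollen probes, and the other splits that hold these 2 arrays gave 2 and 4. Splits that hold both arrays of the shared slide without coronatine 2 gave 5, 3 and 2 lists, and the real comparison called 7 with the slide as a random block.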

How the results depend on the processing

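The settings without control 2 and coronatine 3, without control 1 and coronatine 2, with the reduced series matrices and with the slide as a random block were chosen only after the results were seen, and all other settings before. The planned estimate of the slide correlation could not be made, since 5 slides over 6 arrays gave none, and the block used a correlation of -0.045 from the deviations of the 2 arrays of the shared slide. The cause of the differences below was not tested. Leaving out arrays also leaves fewer samples, although the count rose to 3830 without control 1. The matrix settings differ in content and not only in processing. The matrix column of control 2 equals the scanner file of coronatine 3, and its column of coronatine 3 equals no scanner file. The matrix without its coronatine 3 column thus still holds a coronatine array among the controls. Of the changed probes that a setting also tested, 100% kept their sign in every limma fit on the scanner files except normexp (96.5%), and 58.4% in the series matrix. These probes had been called on the same arrays, so a high share on the scanner files was largely set in advance. Signal over background limits dim genes, since 144 changed probes had only a bound in 1 group. Without the filter on dim probes 51 of the 86 named genes no longer passed, while the 70 that were well above background on all arrays all passed among such probes alone. No scaling moved the median of all probes by more than 0.1 log2 units. Quantile scaling changed no list's call, and the ribosomal, histone, floral identity and jasmonate signalling lists kept their calls in all tests on the scanner files except the estimated correlation. Their medians there ran from -0.291 to -0.212, -0.368 to -0.195, -0.367 to -0.232 and 0.084 to 0.501, without the settings that leave out more than 1 array. The 0.084 of jasmonate signalling came with normexp, whose offset of 50 pulls dim signals together.

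For counts of changed probes, main value 3470, the count was 739 without a filter, 5285 with array weights, 7670 with significance analysis of microarrays and 1850 without control 1 and coronatine 2. It was 0 by limma in the series matrix, in the matrix without its coronatine 3 column, in the matrix without its control 2 and coronatine 3 columns and in the scanner files without control 2 and coronatine 3, where 204, 1246, 5336 and 5367 probes had an unadjusted p under 0.05. Changes of at least 2-fold, main value 989, numbered 295 with normexp, 502 without a filter, 62 with treat and 0 in those same 4 settings. Called lists, main value 8, numbered 18 in the series matrix, 0 with an estimated correlation and 28 by fry in either direction. Leaving out 1 array gave 43 to 3830 changed probes, 43 to 1085 at least 2-fold changes and 6 to 10 lists. The lowest counts of probes came without coronatine 1.

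Replicate numbers are shared by the groups, but the correlations of same-numbered deviations were 0.029, 0.13 and 0.073, so the numbers were not taken to pair the samples. With the replicate number as a block, 1881 probes changed, 1011 higher and 870 lower, and the gibberellin list was called (median -0.31, adjusted p of 0.0280). The block changed no other list's call.

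With normexp, the lists of jasmonate biosynthesis (median 0.16), cell wall loosening (0.016), auxin response (-0.024) and cuticle lipids (0.069) were called and NAC factors (-0.23) were not. Median centring lost aquaporins (0.32). The 75th percentile over detected probes called jasmonate biosynthesis (0.24) and cell wall loosening (0.19). Without a filter jasmonate biosynthesis (0.20) was called and NAC factors (-0.27) were lost. With probes detected on all arrays cell wall loosening (0.19) was called and NAC factors (-0.25) were lost. A floor lost terpenoids (0.26), an intensity trend called cell wall loosening (0.19), and array weights called jasmonate biosynthesis (0.26) and lost NAC factors (-0.19). The slide as a random block called flavonoids (0.087) and lost aquaporins (0.29) and NAC factors (-0.27). Significance analysis of microarrays called flavonoids (0.092) and lost aquaporins (0.28). Counting all annotated probes lost terpenoids (0.26) and aquaporins (0.16). Fry called WRKY factors (-0.12), auxin response (0.11) and gibberellin (-0.31) and did not call NAC factors (-0.27), aquaporins (0.28) or the phenylpropanoid list (-0.47). Camera with estimated correlations lost all 8 calls, with medians of -0.27 for NAC factors, 0.28 for aquaporins, -0.27 for ribosomal proteins, -0.30 for floral identity, -0.24 for histones, 0.42 for jasmonate signalling, -0.47 for phenylpropanoids and 0.40 for terpenoids. The estimates were -0.0084 for jasmonate signalling, -0.0085 for terpenoids, -0.0099 for floral identity and 0.0143 for histones. They were 0.28 for NAC factors, 0.32 for aquaporins, 0.31 for ribosomal proteins and 0.30 for phenylpropanoids. Where the estimate lay below the preset 0.01, the size of the correlation does not account for the lost call.

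Without control 1 and coronatine 2, jasmonate biosynthesis (0.30) and cuticle lipids (0.18) were called and NAC factors (-0.22) were lost. Terpenoids were lost without control 2 and coronatine 3 (0.35), in the matrix without both those columns (0.36) and in the matrix without its coronatine 3 column (0.16), where cell wall loosening (0.17) and cuticle lipids (0.15) were called. Over the settings that leave out 1 array, the medians ran from 0.11 to 0.30 for jasmonate biosynthesis, 0.25 to 0.45 for terpenoids, 0.10 to 0.21 for cell wall loosening, 0.19 to 0.36 for aquaporins, -0.37 to -0.21 for NAC factors, -0.34 to -0.20 for gibberellin and 0.071 to 0.229 for cuticle lipids. Between the 2 arrays of the shared slide, aquaporins were at -0.014, opposite to their median over all arrays, jasmonate biosynthesis at -0.007, the nectary gene at -0.84 and the allene oxide cyclase probes at 0.18 (Na_454_42716) and -0.83 (Na_454_02007). The called lists lay there at 0.37 for jasmonate signalling, 0.36 for terpenoids, -0.60 for phenylpropanoids, -0.28 for ribosomal proteins, -0.16 for histones, -0.39 for floral identity and -0.61 for NAC factors. The allene oxide cyclase probe Na_454_42716 passed with normexp (0.40), the 75th percentile over detected probes (0.45), an intensity trend (0.45), array weights (0.48) and significance analysis of microarrays (0.45).

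The series matrix has a coronatine 3 column that matches none of the scanner files and a control 2 column that equals the scanner file of coronatine 3. In it the lists of MYB factors (-1.02), photosynthesis (-2.43) and sugar metabolism (-0.58) were called in their direction, and jasmonate signalling (-0.076) was not. The direction of the list test turned for aquaporins (-0.995), auxin response (-0.42), cell wall loosening (-1.05), cuticle lipids (-1.48), ribosomal proteins (0.34), ethylene synthesis (-0.45), flavonoids (-0.68), anti-herbivore proteins (-0.87), pathogenesis-related proteins (-0.76), pollen and anther (-1.996) and terpenoids (-0.67). The medians of the ethylene, anti-herbivore, pathogenesis-related and pollen lists were below 0 in both sets of values. Of the named genes none of the 86 passed there, and 30 had the opposite sign. These were 1A11_PRUMU (-1.43), ACCO3_CUCME (-1.11), ACCO_PRUMU (-3.13), APRR7_ARATH (-0.016), CB21_LEMGI (-2.91), CHI4_PHAVU (-0.14), CHS2_SOLTU (-0.41), CINS_ARATH (-1.74), DFRA_HORVU (-1.92), E13I_TOBAC (-2.08), GAO1B_WHEAT (0.73), HMDH3_SOLTU (-0.59), IAA5_ARATH (-3.03), ICI1_SOLLC (-0.72), ICID_SOLTU (-0.87), IP2X_SOLTU (-2.83), LINS_ARATH (-0.50), NAC29_ARATH (-1.45), PIP27_ARATH (-1.30), PR5_ARATH (-4.34), RL10_SOLME (0.27), RL132_BRANA (0.36), RL14_PEA (0.31), RNS6_NICAL (-3.05), RNS7_NICAL (-3.28), TIP11_ORYSJ (-3.10), TIP2_TOBAC (-1.87), UFOG_SOLME (-0.11), WRK44_ARATH (0.44) and XTH20_ARATH (-0.53).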

Other observations

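The scan of entry-name families and the reading of laccases were chosen only after the results were seen, while the bound for the secondary wall list was written before its value was computed. Of 10 entries of laccases, which polymerise lignin monomers in the cell wall, 5 fell with coronatine, 1 rose and 4 were not called. LAC4_ARATH fell by 1.97 (SE 0.32), LAC16_ORYSJ by 1.22 (SE 0.20) and LAC11_ORYSJ by 0.95 (SE 0.22), beside LAC10_ARATH and LAC2_ARATH of the report, and LAC11_ARATH rose by 1.10 (SE 0.13) on the brightest of its probes (Na_454_00157), while of its dimmer probes 1 rose and 3 fell. Among 194 families of entry names, 5 were called by camera, all lower. They were 45 large and 26 small ribosomal subunit proteins (medians -0.28 and -0.24), 22 histones (median -0.48, with 12 lower and 0 higher), 12 AGAMOUS-like factors (median -0.46, with 5 lower and 0 higher) and the laccases (median -1.12, adjusted p of 0.0318). With an estimated correlation 0 of the families were called, with an adjusted p of 0.942 for each of the 5. Arabinogalactan proteins, with 5 of 16 higher, had a median of 0.42 and were not called (adjusted p of 0.106).

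A hypothesis from the laccases is that a secondary wall programme may have been lower with coronatine. It was tested on a list of 42 secondary wall entries that left out laccases, COBL4 and NAC7, of which 10 genes were tested, with a median of -0.24, 0 higher and 3 lower by limma. The cellulose synthases CESA7_ARATH and CESA4_ARATH, which build secondary walls, had differences of -1.65 (SE 0.21) and -1.47 (SE 0.18), and FLA11_ARATH fell by 1.74 (SE 0.25). CESA8_ARATH, of the same complex, had a difference of -0.14 (SE 0.12, adjusted p of 0.452) on the brightest of its probes, while 2 dimmer probes fell, by 1.83 (Na_454_13192) and 1.58 (Na_454_01496). FLA12_ARATH had a difference of 0.03 (SE 0.17). The median lay between the bounds set for and against, so the test left the hypothesis undecided.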
